A study of Mus musculus with 9 samples.

How the data were processed

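PolyA RNA was sequenced from N2A cells, a mouse neuroblastoma line, 48 hours after transfection with pools of small interfering RNAs, per the labels. The labels place 9 libraries in 6 groups. In the first experiment 1 library each was made after knockdown of Mbnl1 together with Mbnl2, after knockdown of Nacc1 and after transfection of a non-targeting pool. In the second experiment 2 libraries each were made after knockdown of Srrm4, after knockdown of Zfp871 and after transfection of a non-targeting pool. Per the labels, RNA was extracted with either of 2 kits; which library had which is not given in the sources used here. The 2 libraries of a group carry the letters a and b in the column names. The labels number the replicates instead, and neither source says which number is which letter, whether the replicates were separate cultures, or whether equal letters share a day.

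The submitters' processing notes give the mouse build mm9 and list CASAVA 1.8 and edgeR, without saying which step each served. Per the series design text, splicing was quantified with vast-tools, which reports for each cassette exon, retained intron and alternative splice site the percent spliced in (PSI), the share of transcripts that include the segment. The vast-tools version, the aligner and the program that counted reads per gene are not given in the sources used here. The deposited gene tables hold raw read counts per gene, per the file headers, with the authors' log2 fold changes against control, and for the second experiment the authors' FDR from edgeR, whose test and filter are not stated. In the filtered splicing tables the authors' deposited PSI values are in percent, with 1 value per condition, beside a TRUE or FALSE column for differential splicing whose rule is not stated. Per the file headers and the values, the primary vast-tools tables hold per library a text cell that ends in the inclusion and exclusion reads of the event. Recomputed as 100 times inclusion over the sum of inclusion and exclusion reads, PSI differed from the authors' deposited values by a median of 0 points in the first experiment. In the second experiment, where the authors give 1 value over both libraries, the median absolute difference from the mean of the libraries was 0.358 to 0.383 points. The 23 columns of per-library values not used here were 21 of PSI and normalised expression and 2 of a trimmed version of the control library a.

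Total counts per library were 50086176 to 63715449 in the first and 44186088 to 61159670 in the second experiment. Cassette exon reads came to 10248921 to 12730045 and 11288781 to 15188778. The median number of reads per exon, among exons with at least 10, was 152 to 185 and 145 to 194. The 10 most abundant genes took 5.61% to 6.27% and 5.84% to 7.33% of the counts. All 21553 genes listed with counts entered the filters below, and 1114 further entries without counts did not.

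For the second experiment, counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood test) in 1 fit to all 6 libraries, so that the 3 groups of 2 share 1 estimate of the spread. The 3 contrasts were each knockdown against the control and the Zfp871 knockdown against the Srrm4 knockdown, without a replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12378 tested genes. Log2 fold changes are from the same fit, with standard errors (SE). Cassette exons were tested on inclusion and exclusion reads, rounded to whole numbers, with the edgeR quasi-likelihood test in the form edgeR documents for paired read classes: a coefficient per library and an inclusion coefficient per group, with 1 dispersion per exon and no trend. Exons needed at least 10 reads in each of the 6 libraries and a PSI from 2 to 98 in at least 1 of them, which left 20266 exons of 6910 genes. A call needed an adjusted p under 0.05 and a difference in mean PSI of at least 10 percentage points. Microexons were defined as 3 to 27 nt long. Retained introns and alternative splice sites were tested with limma 3.58.1 (trend) on the logit of PSI with an offset of 1, since their reads do not always come in a pair of classes.

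Each group of the first experiment holds 1 library, so no p-value is given for it. An exon passed the size rule with at least 20 reads in all 3 libraries, a PSI difference of at least 20 percentage points and 95% exact (Clopper-Pearson) intervals that did not overlap. A gene passed with at least 50 counts in 1 of the libraries compared and a log2 fold change of at least 1 in size (TMM factors, prior count 2). Intervals for counts are 95% exact Poisson intervals. All intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

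The samples, contrasts, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The lists were: tissue-regulated splicing factors, SR proteins and relatives, hnRNP proteins, core spliceosome, neuronal genes, REST target genes, axon guidance and adhesion, DNA replication, mitosis, p53 target genes, interferon response, unfolded protein and amino acid response, cholesterol biosynthesis, glycolysis and hypoxia, immediate early and MAP kinase feedback, glial markers, fibroblast and mesenchymal markers, epithelial markers, immune markers, cytosolic ribosomal proteins and oxidative phosphorylation. A further pair of lists held host genes of exons, those of Srrm4-dependent and other neural microexons and those of Mbnl target exons. Lists can share members, so their results are not independent. Syn1, Stmn2, Vgf, L1cam and Cplx2, among others, are in both the neuronal and the REST list. Clasp2 and Spna2 are in both host lists. Members renamed since mm9 were matched by gene identifier; Hmgcs1 and Rps18 were not found among the genes with counts. Lists with 5 or more tested genes were tested with camera (preset correlation) and adjusted over the lists. In the first experiment the median of each list was placed among the medians of 10000 random lists of equal size matched on expression. Random genes were drawn independently, so the ranges cover neither genes that move together nor the spread between libraries. Fisher's exact test, two-sided, compared microexons with longer exons and exons of the host lists with other tested exons.

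Genes and exons are named by that fixed rule: the targeted genes and their relatives; per knockdown of the second experiment up to 10 higher and 10 lower called genes of largest fold with at least 1 CPM on average; up to 4 members per list; up to 10 higher and 10 lower called exons; per knockdown of the first experiment up to 8 genes and 8 exons per direction; the exons shared by both knockdowns with the largest sum of differences; and any splicing factor that passed. Unnamed or clone-like symbols were left out. Some genes that the rule names are not reported here. For the first experiment, which has no p, list members were taken by the size of their fold change. Genes called in both knockdowns or in opposite directions, and exons recurring across experiments, were picked after their values were seen. The exons of Fbxo25, Flnc, Spag9 and Dst under Zfp871 knockdown are named from calls of the likelihood ratio test, which was added after seeing the data.

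The shared control libraries make chance values of 2 comparisons move together. Overlaps and correlations across exons or genes are therefore given beside values simulated for unchanged groups against the same control, and for the exons of the second experiment also beside a recalculation with no library in common. The simulated libraries of the first experiment carry counting error only, and those of the second vary independently of one another. Tested on simulated data with the spread of these libraries, the gene test recovered 67.7% of genes changed by 1 on the log2 scale and 90.8% of those changed by 2, with 11 false calls. For the exon test the simulation gave all exons the same median overdispersion (0.00124) and changed only exons of medium control PSI. There it recovered 37% of exons changed by 20 points and 92% of those changed by 40 points, with 0 false calls. These shares need not hold for exons whose libraries vary more or whose control PSI is near either end. The size rule recovered 82.5% of exons changed by 30 points, with 6 false ones.

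After the planned exon test had been seen to call 25, 0 and 0 exons, other forms of it were tried on the same data: a likelihood ratio test in edgeR with the same dispersions, with and without a block for the column letter, limma with that block, and the quasi-likelihood test with trended dispersions in legacy and robust form. Only the likelihood ratio test gave many more calls. It does not carry the uncertainty of a spread estimated from 2 libraries per group. In 20 simulated sets of unchanged groups that kept each exon's own spread it made 25.8 calls on average (15 to 43), of which 0.35 were lowered microexons, while the quasi-likelihood test made 0. In a fit with a term for the letter, it called 119 exons between the letters a and b, 390 under Srrm4 and 308 under Zfp871 knockdown. Its calls are given as a second, more permissive reading, named as such wherever they are printed. Also chosen after seeing the data were the camera test of microexons, their comparison with 10000 sets of longer exons matched on control PSI, and the splits of the libraries by letter.

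Alternatives planned in advance were RLE size factors, DESeq2 1.42.0, no filter or a stricter filter on counts, a block for the column letter, an added fold threshold, only the 4 libraries of a comparison, other read minimums and PSI thresholds, limma on logit PSI, only exons of the authors' filtered table, camera with an estimated correlation, fry, and leaving out each library in turn. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Positions are those of the deposited tables; a gene annotation for a newer mouse build served for matching names only.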

Results

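Gene expression and alternative splicing were measured by sequencing polyA RNA from N2A mouse neuroblastoma cells 48 hours after siRNA transfection. Of the 9 libraries, 3 form the first experiment, with 1 library each after knockdown of Mbnl1 together with Mbnl2, knockdown of Nacc1, and transfection of a non-targeting pool. The other 6 form the second experiment, with 2 libraries each after knockdown of Srrm4, knockdown of Zfp871, and transfection of a non-targeting pool. Total read counts were 50086176 (Mbnl1 and Mbnl2 knockdown), 61038964 (Nacc1 knockdown) and 63715449 (control) in the first experiment. In the second they were 45633036 and 48505982 (control), 44186088 and 61159670 (Srrm4 knockdown) and 44228278 and 51271599 (Zfp871 knockdown), for the libraries with the letters a and b. Mbnl1, Mbnl2 and Srrm4 encode regulators of alternative splicing, Nacc1 a transcriptional regulator with a BTB domain and Zfp871 a zinc finger protein. The series title names the question: how transcription factors act on networks of regulated splicing, which here means whether loss of Zfp871 or Nacc1 shifts exons that also shift when a splicing factor is lost. Since the labels do not say whether the libraries of a group came from separate cultures, p-values measure a spread between libraries that may be technical.

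Each targeted gene was lower in its own knockdown, and Srrm4 was also lower in both Zfp871 knockdown libraries. Srrm4 (ENSMUSG00000063919), which promotes inclusion of neuronal microexons, stood at 67.8 and 95.6 CPM (read counts scaled to library size) in the control libraries a and b, at 29 and 25.5 in its knockdown, and at 45.4 and 52.8 in the Zfp871 knockdown. Its log2 fold change was -1.59 (SE 0.19, n = 2 per group, edgeR adjusted p = 0.0222) in its own knockdown, with -1.23 and -1.89 within the letters a and b. Under Zfp871 knockdown it was -0.73 (SE 0.19, edgeR adjusted p = 0.099, not called), with -0.57 and -0.85 within the letters. The authors' deposited table lists this change as -0.72 with an FDR of 0.016. Zfp871 (ENSMUSG00000024298) stood at 17.9 and 25.9 CPM in control, at 7.26 and 4.99 in its knockdown (log2 fold change -1.84, SE 0.25, edgeR adjusted p = 0.0271) and at 23.3 and 23.2 in the Srrm4 knockdown (0.09, edgeR adjusted p = 0.857). The Srrm4 call was lost without control library b, where the change was -1.3, without Srrm4 knockdown library b (-1.52), and with only the 4 libraries of its comparison (-1.59). The Zfp871 call was lost without control library b (-1.52), knockdown library a (-2.1) or knockdown library b (-1.6), with a lone library assumed to vary like the other groups.

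In the first experiment Mbnl1 (ENSMUSG00000027763) fell from 124 normalised CPM in control (95% exact Poisson interval 121 to 127) to 45.2 (43.4 to 47.1) in the Mbnl1 and Mbnl2 knockdown, past the size rule. Mbnl2 (ENSMUSG00000022139) fell from 65.7 (63.7 to 67.7) to 18.2 (17 to 19.4). Nacc1 (ENSMUSG00000001910) fell from 208 (205 to 212) to 52 (50.2 to 53.8) in its knockdown and stood at 223 (219 to 227) in the Mbnl knockdown. In the Nacc1 knockdown Mbnl1 stood at 82.7 (80.4 to 85), a log2 fold change of -0.59 that is short of the size rule, and Mbnl2 at 65.6. Srrm4 stood at 85.1 in control, 86.2 and 86.6 in the knockdowns, and Zfp871 at 47.8, 47.9 and 54.5. These groups have no replicates, and the intervals cover counting error only. Among relatives, Srrm3 fell under Srrm4 knockdown (log2 fold change -0.62, SE 0.11, edgeR adjusted p = 0.0341), stood at -0.15 (adjusted p = 0.466) under Zfp871 knockdown, and at -0.04 and 0.11 in the first experiment. Mbnl3, with 0 to 13 counts per library, and Nacc2, with 13 to 56, were near the floor.

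**Figure D1:**
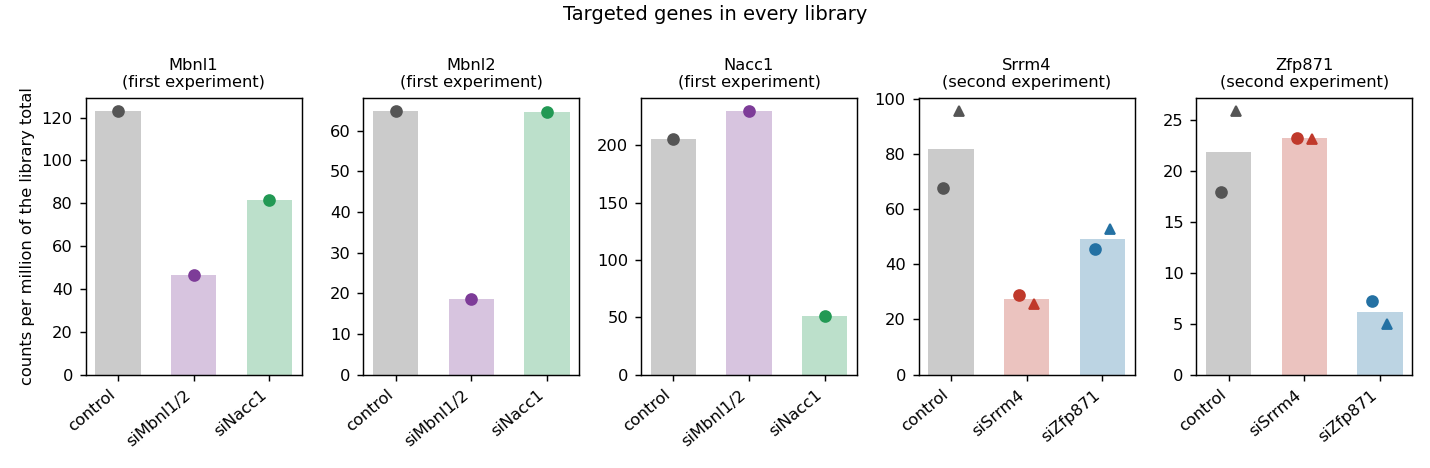
Targeted genes as CPM of the library total (vertical axis, from 0), each in the libraries of its own experiment; bars are group means, circles the only library or letter a, triangles letter b. Srrm4 in the Zfp871 knockdown (45.4 and 52.8) lies between its control (67.8 and 95.6) and its own knockdown (29 and 25.5).

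Knockdown of Srrm4 lowered inclusion of short exons. A 24-nt exon of Clasp2, which encodes a protein of microtubule plus ends, fell from a PSI of 78% ± 3.5 (SD, n = 2) to 9.4% ± 1.3 (chromosome 9, 113787868 to 113787891, mm9; edgeR adjusted p = 0.0278). A 15-nt exon of Vav2, a guanine nucleotide exchange factor, fell from 82.1% ± 3.1 to 18.4% ± 1.8 (chromosome 2, 27140359 to 27140373; edgeR adjusted p = 0.0314). A 6-nt exon of Snap91, a clathrin assembly protein of synapses, fell from 72.4% ± 3.8 to 19% ± 5.4 (chromosome 9, 86707915 to 86707920; edgeR adjusted p = 0.0164). Exons of Sh3glb1 (24 nt, PSI difference -51.9 points), Snx14 (27 nt, -51.7), Dock4 (27 nt, -51.7), Scyl2 (12 nt, -49.7), Med24 (57 nt, -45.4), Pacsin2 (6 nt, -40.6) and Myo5a (9 nt, -40) fell as well. Both knockdown libraries lay below both control libraries for all 10 of these exons.

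Of 20266 tested cassette exons, the edgeR quasi-likelihood test called 25 lower and 0 higher under Srrm4 knockdown; 1157 had an unadjusted p under 0.05. Of the 25, 18 were microexons and 7 longer, which is 3.5% of the 510 tested microexons and 0.04% of the 19756 longer exons (Fisher's exact test, two-sided, odds ratio 103, 95% interval 40.9 to 292, p = 4.98e-24). Lengths divisible by 3 made up 88% of called and 40.7% of other exons. Host genes of Srrm4-dependent and other neural microexons, a list fixed in advance, held 10 of the calls among 421 exons (Fisher's exact test, odds ratio 32.2, adjusted p = 1.33e-10), such as Eif4g1 (21 nt, from 50.8% to 14.6%) and Kif1b (18 nt, from 97.2% to 60.6%); 39 exons were called when adjusted over the list alone. Host genes of Mbnl target exons held 1 call, the Clasp2 exon, among 331 exons (Fisher's exact test, adjusted p = 0.676), and 12 when adjusted over the list alone; a 15-nt exon of Spna2, which encodes alpha spectrin, was at -30.5 points (edgeR adjusted p = 0.0578). The authors' deposited table marks 24 of the 25 exons as TRUE, and 311 of all exons tested here. Without control library a, control library b, Srrm4 knockdown library a or Srrm4 knockdown library b the count was 0, with a lone library assumed to vary like the other groups; the Clasp2 difference was -65.2 and -72 points within the letters a and b. The more permissive likelihood ratio test, added after seeing the data, called 55 exons higher and 227 lower (119 of them microexons) against 25.8 calls on average in simulated sets of unchanged groups. It called 230 without control library a, 243 without control library b, 259 without Srrm4 knockdown library a and 193 without Srrm4 knockdown library b, with at least 89 lowered microexons each time.

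**Figure D2:**
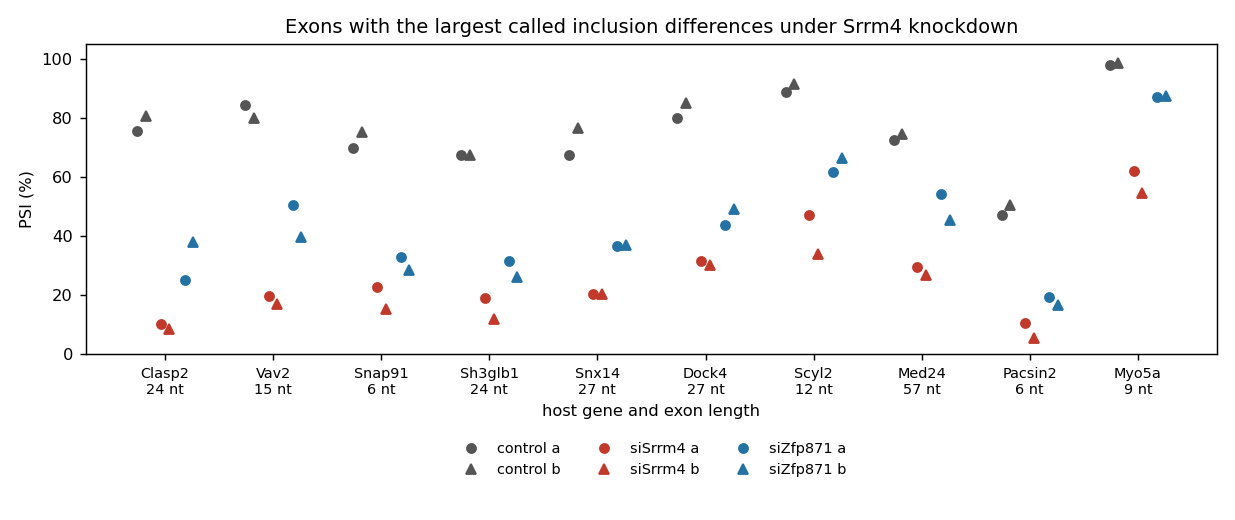
PSI in percent (vertical axis) of the 10 exons of largest decrease called under Srrm4 knockdown, for each of the 6 libraries of the second experiment; points are single libraries, coloured by group. The Clasp2 exon falls from 75.5 and 80.5 in control to 10.4 and 8.5 in the Srrm4 knockdown, with 25 and 38 in the Zfp871 knockdown.

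As a class, microexons were lower under Srrm4 knockdown whether or not they were called one by one. Their median PSI difference was -2.59 points against 0 for longer exons, and 72.9% of them lay below control against 46.6% of longer exons. Within the letters a and b the microexon medians were -2.47 and -3.68 points, with 0 for longer exons. In a camera test added after seeing the data, microexons ranked lower than other exons with p = 2.97e-19, and with p = 0.00658 with an estimated correlation. Sets of longer exons matched on control PSI, also added, had a median difference of 0.16 points (lowest -0.26 and highest 0.74 in 10000 draws). By the likelihood ratio test 26.7% of exons of 3 to 15 nt and 21% of those of 16 to 27 nt were lower, then 2.3% of those of 28 to 51 nt and at most 0.6% of longer ones.

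In gene expression, 5 of 44 listed neuronal genes fell under Srrm4 knockdown and 1 rose. Cplx2, a complexin that acts in vesicle fusion, fell by 1.65 on the log2 scale (SE 0.14, n = 2 per group, edgeR adjusted p = 0.0178), and its relative Cplx1 fell by 1.12 (SE 0.11, adjusted p = 0.0184). Mtap2, the gene of microtubule-associated protein MAP2, fell by 1.07 (SE 0.11), Nefh, the heavy neurofilament chain, by 1 (SE 0.08), and Syn1, a synapsin, by 0.63 (SE 0.09). Sncg (-2.21, SE 0.38), which encodes gamma-synuclein, and Pde9a (-2, SE 0.2), a cyclic GMP phosphodiesterase, fell too, as did Zfp385a (-1.85), Cpne1 (-1.79), Esx1 (-1.75), Reep2 (-1.73), Dnajc6 (-1.7), Napb (-1.62) and Dbx2 (-1.61). Higher genes included the collagens Col28a1 (2.86, SE 0.33) and Col4a1 (1.77, SE 0.16), Glt8d2 (2.55), Fam92b (2.4), Hcrtr1 (1.9), Csmd1 (1.49), Lepre1 (1.34), the apoptosis effector Bak1 (1.33), Fbxo36 (1.32) and the cyclin Ccnd3 (1.28). Of 12378 tested genes 175 rose and 407 fell, of which 46 and 92 changed at least 2-fold, and 3072 had an unadjusted p under 0.05. All counts here are from a fit without a term for the column letter. Libraries of equal letter deviated together from their group means (r = 0.749, 0.662 and 0.637 between pairs of groups). With a block for the letter many more genes were called, as given further below, but no source says what the letters pair. Over all tested genes, 53.7% had both knockdown libraries on the same side of both controls, which chance gives for 33.3%. The count fell to 20 without control library a, to 0 without control library b, to 180 without Srrm4 knockdown library a and to 0 without Srrm4 knockdown library b.

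Several fixed gene lists leaned one way under Srrm4 knockdown, although with an estimated correlation none of the camera calls held in either knockdown. Among 30 tissue-regulated splicing factors 5 fell and 0 rose (camera adjusted p = 0.000356, median -0.26; adjusted p = 0.244 with an estimated correlation): Srrm4 itself, Rbms3 (-1.4, SE 0.13), the neuronal RNA-binding genes Elavl4 (-0.89, SE 0.09) and Elavl3 (-0.49, SE 0.08), and Srrm3, with 7 lower when adjusted over the list alone. Among 44 neuronal genes 5 fell and 1 rose (camera adjusted p = 0.000275; 0.244 with an estimated correlation), with 11 and 2 when adjusted over the list alone; the one that rose, singled out after its values were seen, was Stmn4. Of 30 REST target genes, which the repressor REST silences outside neurons, 5 fell, with 11 when adjusted over the list alone (camera adjusted p = 2.4e-05; 0.244 with an estimated correlation). The 40 DNA replication genes had a median of -0.18, with Rrm2 (-0.81, SE 0.1) and Gins2 (-0.49, SE 0.09) lower (camera adjusted p = 0.000275; 0.617 with an estimated correlation; 2 lower when adjusted over the list alone). Cholesterol biosynthesis had 0 calls of 23 and a median of -0.18 (camera adjusted p = 0.00206; 0.617 with an estimated correlation), with Srebf2 at -0.45 (edgeR adjusted p = 0.0696).

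Higher lists under Srrm4 knockdown were oxidative phosphorylation, with 43 of 44 fold changes positive, a median of 0.27 and 1 gene that rose, Uqcrfs1 (0.58, SE 0.1), or 11 when adjusted over the list alone (camera adjusted p = 6.54e-10; 0.483 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.15 over 56 genes (camera adjusted p = 0.000291; 0.617 with an estimated correlation), although the only member called, also when adjusted over the list alone, was Rpl29, which fell by 0.96. The unfolded protein and amino acid response list had a median of 0.2 over 39 genes (camera adjusted p = 0.000291; 0.617 with an estimated correlation), with the amino acid transporter Slc7a3 higher (0.84, SE 0.14), 1 also when adjusted over the list alone, and the chaperone Hspa5 at 0.47 (edgeR adjusted p = 0.0783). Among 24 hnRNP proteins Hnrnph2 rose (0.69, SE 0.1) while Hnrnph1 was at -0.5 (edgeR adjusted p = 0.0605), and the list median was -0.05 (camera adjusted p = 0.287). Single members fell in axon guidance and adhesion (Nrp2, -0.65; list median -0.26, camera adjusted p = 0.124), p53 target genes (Mdm2, -0.91; -0.06, 0.64), interferon response (Trim25, -0.77; median 0.13, 0.734) and immediate early and MAP kinase feedback genes (Ccnd1, -0.6; -0.15, 0.287). No member was called among SR proteins (median -0.11, camera adjusted p = 0.12), core spliceosome (0.05, 0.287), mitosis (-0.04, 0.734), glycolysis and hypoxia (0.18, 0.496), or the glial (5 genes tested, -0.64, 0.287) and mesenchymal markers (9 genes tested, -0.43, 0.381). Epithelial and immune markers had 3 and 1 tested genes, too few for a list test; Grhl2 was at 0.37 and Cd68 at 0.79, and neither was called.

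Knockdown of Zfp871 lowered 7 of 44 listed neuronal genes and raised 1 (camera adjusted p = 1.46e-05; 0.322 with an estimated correlation); of the 7, Cplx2 was also called under Srrm4 knockdown. Dbh, the enzyme that makes noradrenaline, fell by 2.24 on the log2 scale (SE 0.27, n = 2 per group, edgeR adjusted p = 0.0232), Scn3b, a sodium channel subunit, by 2.07 (SE 0.25), and Gfra1, a receptor for the growth factor GDNF, by 1.91 (SE 0.28). Nwd1 (-2.78, SE 0.33), Ppfibp2 (-2.71), Papss2 (-2.19), Pde9a (-2.12), St6galnac5 (-2.06), Gpr22 (-1.99) and Dazl (-1.92) fell too. Acta1, skeletal muscle actin, rose by 3.93 (SE 0.31, edgeR adjusted p = 0.0192) and Nes, the intermediate filament nestin of neural progenitors, by 1.65 (SE 0.1, adjusted p = 0.0156). Prnd (2.96), Timp3 (2.01), Padi4 (1.77), Pdlim3 (1.66), Irak2 (1.54), Fos (1.5), Tmem123 (1.48) and Amotl2 (1.48) rose as well. Of 12378 tested genes 93 rose and 265 fell, 27 and 84 of them at least 2-fold, and 2613 had an unadjusted p under 0.05. Over all tested genes 50.5% had the groups apart (33.3% by chance). These counts too are from the fit without a term for the letter, and with a block for it many more genes were called. The count fell to 29 without control library a and to 0 without control library b, without Zfp871 knockdown library a or without Zfp871 knockdown library b.

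The 44 neuronal genes had a median of -0.25 under Zfp871 knockdown, with 16 lower and 3 higher when adjusted over the list alone. The synapsin gene Syn2 (-1.01, SE 0.12) and the adhesion gene L1cam (-0.74, SE 0.1) were among the 7 that fell; the one that rose, singled out after its values were seen, was Insm1. REST target genes had 3 lower of 30, Cplx2, Stmn2 and L1cam, with 5 when adjusted over the list alone (median -0.18, camera adjusted p = 0.00335; 0.47 with an estimated correlation). Of 30 tissue-regulated splicing factors 3 fell, Rbms3 (-1.35, SE 0.13), Celf4 (-1.09, SE 0.18) and Nova1 (-0.94, SE 0.16), with 8 lower and 2 higher when adjusted over the list alone (median -0.07, camera adjusted p = 0.0614). In axon guidance and adhesion Plxnb2 (-1.19, SE 0.1) and Nrp2 (-0.75, SE 0.13) fell, 2 also when adjusted over the list alone (median -0.29, camera adjusted p = 0.0284; 0.47 with an estimated correlation). The p53 target genes Ccng1 (-1.46, SE 0.19) and Apaf1 (-1.05, SE 0.19) fell (list median -0.23, camera adjusted p = 0.158), as did the interferon-induced Ifi35 (-1.09, SE 0.16; list median -0.33, 0.0726) and the mesenchymal marker Fn1, fibronectin (-1.18, SE 0.1; list median -0.54, 0.129). Of the immediate early list Fos and Phlda1 (1.18, SE 0.2) rose (median 0.08, camera adjusted p = 0.245). Atf5 (0.55, SE 0.1) rose in the unfolded protein and amino acid response list, with 3 higher and 1 lower when adjusted over the list alone (median 0.09, camera adjusted p = 0.00711; 0.65 with an estimated correlation).

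Several lists had no called member under Zfp871 knockdown. Core spliceosome (median 0.14, camera adjusted p = 0.0022), DNA replication (0.1, 0.00534), mitosis (0.08, 0.0327) and oxidative phosphorylation (0.13, 0.000219) ranked higher than other genes, and cholesterol biosynthesis lower (-0.16, 0.00534), with adjusted p = 0.65, 0.65, 0.65, 0.625 and 0.619 with an estimated correlation. Members short of a call there included Ndufa4 at 0.34 (edgeR adjusted p = 0.0795), Snrnp40 at 0.43 (0.093) and Fdps at -0.3 (0.0983). No shift was called for SR proteins (median 0.06, camera adjusted p = 0.245), hnRNP proteins (0.08, 0.0812), glycolysis and hypoxia (-0.07, 0.905), glial markers (-0.55, 0.129) or cytosolic ribosomal proteins (0, mean -0.01, ranked up by camera, 0.905). The epithelial marker Grhl2 was at 0.23 and the immune marker Cd68 at 0.57, neither called.

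**Figure D3:**
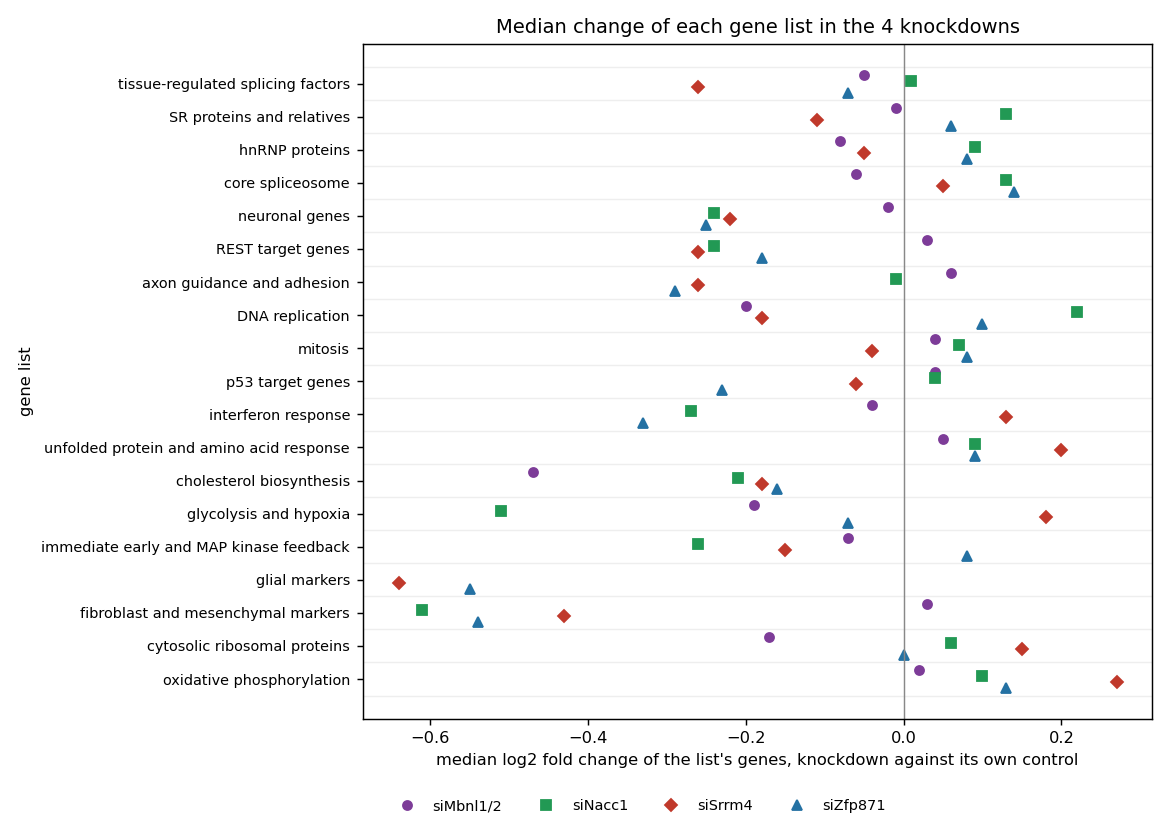
Median log2 fold change (horizontal axis) of each fixed gene list in the 4 knockdowns, each against the control of its own experiment; each point is 1 list in 1 knockdown. Cholesterol biosynthesis lies below 0 in all 4 (-0.47, -0.21, -0.18 and -0.16). Of the 4 medians of glycolysis and hypoxia, that of the Nacc1 knockdown is the lowest (-0.51).

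No single exon was called under Zfp871 knockdown, yet microexons as a class were lower. The edgeR quasi-likelihood test called 0 of 20266 exons (smallest adjusted p 0.182; 946 at an unadjusted p under 0.05; limma on logit PSI 0). The Clasp2 microexon that fell under Srrm4 knockdown was at 31.5% ± 9.2 (SD, n = 2) against 78% ± 3.5 in control, and the Snap91 microexon at 30.8% ± 3.1 against 72.4% ± 3.8 (edgeR adjusted p = 0.566 and 0.291, not called). Median PSI differences were -3.03 points for microexons and -0.23 for longer exons, and 77.6% of microexons lay below control against 54.2% of longer exons. In the camera test added after seeing the data microexons ranked lower with p = 7.58e-14, and with p = 0.011 with an estimated correlation. Within the letters a and b the microexon medians were -2.7 and -4.03 points, with 0 for longer exons.

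The likelihood ratio test, added after seeing the data, called 19 exons higher and 166 lower under Zfp871 knockdown, against 25.8 calls on average in simulated sets of unchanged groups. Of the lower exons 75 were microexons (Fisher's exact test, odds ratio 37.2, 95% interval 26.6 to 51.9). Among the lower ones were a 34-nt exon of Add1, which encodes an adducin of the membrane skeleton (from 64.9% ± 1 to 41.8% ± 0.5), and microexons of Fbxo25 (27 nt, from 52.1% ± 1.4 to 15.9% ± 3.4), Ergic3 (15 nt, from 45.3% ± 3.2 to 15.3% ± 3) and the dynamin gene Dnm1 (12 nt, from 95% ± 0.9 to 80.1% ± 2.8). Higher ones included exons of Flnc (99 nt, 36.1 points), which encodes a filamin, Spag9 (39 nt, 19.2) and Dst (111 nt, 18.9). Of these calls 150 are marked TRUE in the authors' deposited table, which marks 251 of the tested exons. Leaving out Zfp871 knockdown library b lowered the count from 185 to 99, and without any other library it was 162 to 178. In a fit with a term for the letter, this test called 308 exons under Zfp871 knockdown and 119 between the letters a and b. The contrast of letters has more libraries per side than that of the knockdown. Host genes of neural microexons held 0 calls by the quasi-likelihood test, 11 when adjusted over the list alone, and 34 by the likelihood ratio test; host genes of Mbnl targets held 0, 0 and 16.

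**Figure D4:**
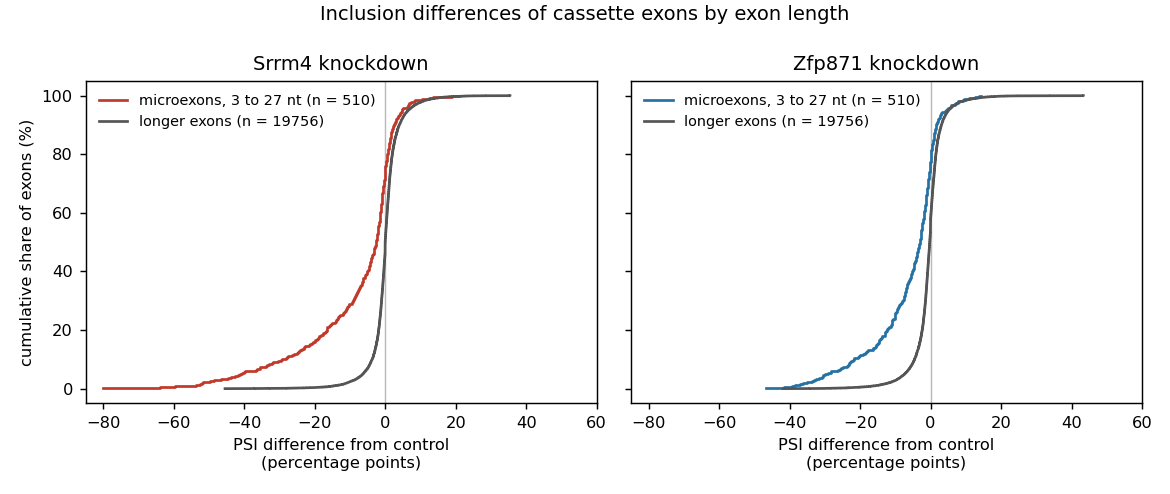
Cumulative share of exons (vertical axis, percent) against the PSI difference from control (horizontal axis, percentage points) for 510 microexons and 19756 longer exons in the Srrm4 and Zfp871 knockdowns. The microexon lines lie to the left of those for longer exons, with medians of -2.59 and -3.03 points.

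The Srrm4 and Zfp871 knockdowns moved many of the same exons. By the likelihood ratio test 104 exons were lower in both, where 1.86 would be shared by independent lists and 4.3 were shared in simulated unchanged groups; 66 of them were microexons. Of 165 exons lower under Zfp871 knockdown by that test, 140 were lower under Srrm4 knockdown than in the control of the first experiment (97.3% of the microexons and 74.7% of the longer exons, against 69% and 50.4% of all tested ones), a comparison chosen after seeing the data. Over all tested exons the sign was the same in 62.9%, where unchanged groups simulated against the same controls gave 66.5%. Across all tested exons, which are not independent replicates, PSI differences correlated with r = 0.56, where unchanged groups simulated against the same controls gave 0.5; the covariance was 13.5 against 6.38. With no library in common the correlation was 0.21 and 0.167 when the control libraries were split, and 0.208 and 0.187 when the letters were. For microexons r was 0.833 (covariance 118 against 9.1 simulated), and with no library in common 0.713, 0.706, 0.659 and 0.654.

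Part of these exons differed between both knockdowns by the likelihood ratio test, added after the data were seen. The quasi-likelihood test called 0 exons between both knockdowns (1080 at an unadjusted p under 0.05; smallest adjusted p 0.176; limma 0), and the likelihood ratio test 169. Of these 169, 79 were higher and 90 lower under Zfp871 than under Srrm4 knockdown, with 29 and 5 microexons among them. Of the 104 shared lower exons 32 differed by the likelihood ratio test, all 32 with the smaller change under Zfp871 knockdown. The Fbxo25 microexon was at -36.3 points under Zfp871 and -29.4 under Srrm4 knockdown (likelihood ratio test of the difference, adjusted p = 0.157). That of Dnm1 was at -14.9 and -6.6 (same test, adjusted p = 0.107). The medians depend on the list: they were -21.48 points under Srrm4 and -13.75 under Zfp871 knockdown over the 227 exons lowered by Srrm4 knockdown, and -19.85 and -19.73 over the 166 lowered by Zfp871 knockdown (likelihood ratio test). The microexon of Kif1b was at -12.3 points under Zfp871 and -36.6 under Srrm4 knockdown (likelihood ratio test of the difference, adjusted p = 1.75e-08) and that of Myo5a at -11 and -40 (adjusted p = 9.94e-11). The Snap91 microexon was at -41.5 and -53.4 (adjusted p = 0.152), and the Add1 exon at -23.1 and -22.7 (adjusted p = 1). The Spna2 microexon, at -30.5 under Srrm4 knockdown, was at -2.8 under Zfp871 knockdown (adjusted p = 3.41e-24).

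In gene expression both knockdowns raised 16 genes (1.31 for independent lists) and lowered 47 (8.71), where unchanged groups, simulated as independent libraries against the same controls, shared 0.1. Picked after their values were seen, Sorl1, a sorting receptor, rose by 2.19 and 2.6 under Srrm4 and Zfp871 knockdown, and Pde9a was at -2 and -2.12. Rbms3, picked likewise, encodes an RNA-binding protein and was at -1.4 and -1.35 (edgeR adjusted p of the difference 0.85). The complexin Cplx2 was at -1.65 and -0.89 and the growth factor Tgfb2 at -0.9 and -1.78, and both differed (edgeR adjusted p = 0.028 and 0.0149). Across the 12378 genes, which are not independent replicates, r was 0.334 and the covariance 0.0624, where simulated unchanged groups gave 0.499 and 0.0502. Tested directly, in the fit without a term for the letter, 684 genes were higher and 690 lower under Zfp871 than under Srrm4 knockdown. That count was 530 without Srrm4 knockdown library a and 0 without Srrm4 knockdown library b, without Zfp871 knockdown library a or without Zfp871 knockdown library b.

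Retained introns and alternative splice sites gave no calls by limma in either knockdown of the second experiment. Of 24790 introns, 11354 alternative acceptor and 7939 alternative donor events, 255, 109 and 132 had an unadjusted p under 0.05 with a difference of at least 10 points under Srrm4 knockdown, and 236, 226 and 95 under Zfp871 knockdown. The smallest adjusted p-values were 0.325 and 0.495; no other tool was run on these events. Median intron retention differed from control by -0.71 and -0.73 points. The count was 21 and 26 without control library a, and 0 without any other library.

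Knockdown of Mbnl1 together with Mbnl2 in the first experiment shifted 193 exons past the size rule. An 18-nt exon of Dst, which encodes the cytoskeletal linker dystonin, fell from 92.3% (95% exact interval 87.3 to 95.9) to 10.2% (6 to 15.3) (chromosome 1, 34353587 to 34353604, mm9). A 130-nt exon of the integrin gene Itga6 fell from 68.9% (66.1 to 71.7) to 7.1% (4.7 to 10) (chromosome 2, 71691591 to 71691720), and a 42-nt exon of Numa1, a spindle pole protein, from 70.7% (66.7 to 74.2) to 8.9% (6.4 to 12). Exons of Cyth1 (3 nt, -60.3 points), Pcnt (-58.1), Arhgef12 (-56.7), Mdm1 (-55.5) and Ank2 (12 nt, -53.4) fell too, past the size rule. Among higher exons were those of Dclk2 (13 nt, from 7.8% to 69.2%), Tacc2 (9 nt, from 10% to 68.3%), Map3k4 (52.5 points), Dgki (51.1), Dennd3 (49), Socs7 (44.7) and Myt1 (44). In the dynamin gene Dnm2 a 139-nt exon fell from 61.7% to 9.9% and another of equal length rose from 40% to 90.5%. Of 17504 variable exons 76 were higher and 117 lower, in 172 genes, with 7 and 19 microexons among them. Host genes of Mbnl target exons, a list fixed in advance, held 30 of these among 304 exons (9.9% against 0.95% of others), and host genes of neural microexons 12 of 384 (3.1% against 1.06%). Microexons as a class had a median of -0.48 points, within the range of random sets of longer exons (-0.87 to -0.05).

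Nacc1 knockdown shifted a set of exons that overlapped with those of the Mbnl knockdown. The Itga6 exon fell to 16.6% (13.9 to 19.7), the Numa1 exon to 19.3% (16.2 to 22.7), and a 45-nt exon of Tbc1d23 from 87.7% (82.6 to 92.1) to 32.3% (25.6 to 40.1), where the Mbnl knockdown had 37.6%. The Dst exon fell to 56.8% (50.2 to 63.5) and the Arhgef12 exon from 79.4% to 32.9%. Other exons moved in the Nacc1 knockdown and not past the rule in the Mbnl knockdown: a 48-nt exon of Uap1, an enzyme of nucleotide sugar synthesis, fell from 86.5% (83.8 to 89) to 28.1% (24.1 to 32.6), with a difference of 2 points in the Mbnl knockdown, and a 129-nt exon of the mTOR regulator gene Tsc2 from 86.2% to 38.9% (-0.6). Golim4 (-47) was lower as well, and Fkbp7 (57.1), Map3k7 (45), Tpm3 (44.8), Clip1 (39), Tmem87b (37.6) and Itpr1 (37.1) were higher. Of the 17504 variable exons 46 were higher and 134 lower, in 159 genes, with 2 and 18 microexons. Host genes of Mbnl targets held 31 of 304 (10.2% against 0.87%), and those of neural microexons 15 of 384 (3.9% against 0.96%), such as a 27-nt exon of Clasp1 (from 39.2% to 73.3%). The median microexon difference was -0.06 points, within the range of random sets (-0.63 to 0.03).

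Past the size rule in both knockdowns of the first experiment were 23 exons higher and 54 lower, with 0 in opposite directions. Independent lists would share 0.2 and 0.896, and unchanged libraries simulated with counting error only against the same control shared 0.2 in all. Across the 17504 exons, which are not independent replicates, r was 0.523 and the covariance 18.2, where simulated unchanged libraries gave 0.467 and 6.55. Both knockdowns share 1 control library. Measured instead against the mean of both controls of the second experiment, 191 of 192 Mbnl and 176 of 179 Nacc1 exons kept their direction, and 133 and 123 kept a difference of at least 20 points. The authors' deposited table marks 590 and 632 exons as TRUE, among which are 144 of the 193 and 142 of the 180 counted here. Among other events past the rule were 51 introns, 13 alternative acceptors and 25 donors in the Mbnl knockdown, and 58, 12 and 14 in the Nacc1 knockdown.

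**Figure D5:**
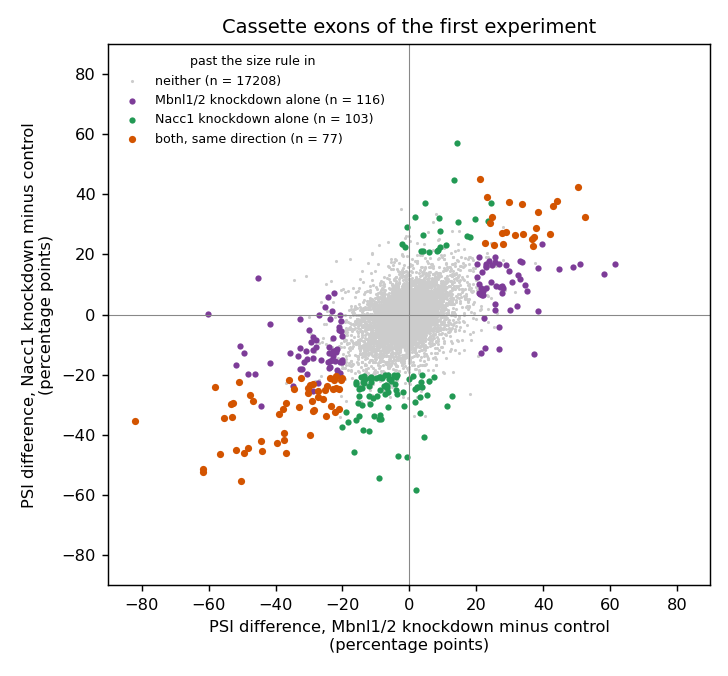
PSI difference from control (percentage points) in the Mbnl1 and Mbnl2 knockdown (horizontal axis) and in the Nacc1 knockdown (vertical axis) for 17504 exons, coloured by the size rule; each point is 1 exon with 1 library per group. The 77 exons past the rule in both lie along the diagonal, and 116 and 103 are past it in 1 knockdown.

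In the Nacc1 knockdown 9 of 32 glycolysis and hypoxia genes and 1 of 44 neuronal genes fell past the size rule. The neuronal enolase Eno2 fell from 97.3 CPM (94.8 to 99.7) to 24.4 (23.2 to 25.7), Aldoc, an aldolase, from 17.7 (16.7 to 18.8) to 4.48 (3.96 to 5.05), and the hypoxia-induced Ankrd37 from 15 to 3.72 and Ndrg1 from 14.8 to 4.15. Of the glycolysis and hypoxia list 0 rose past the rule, and its median of -0.51 lay below the range of random lists (-0.06 to 0.12). This range and those below treat genes as independent and leave out the spread between libraries. Stmn4, a stathmin, fell from 29.2 (27.9 to 30.6) to 7.1 (6.44 to 7.8). Neuronal genes and REST target genes (0 of 28 past the rule), lists that share members, both had a median of -0.24 (random lists -0.04 to 0.11 and -0.05 to 0.13). Cplx2 stood at -1 on rounding, short of the rule, Vgf at -0.95 and Syn1 at -0.87. Other lists outside the range of random lists were cholesterol biosynthesis (-0.21), immediate early and MAP kinase feedback (-0.26, with Ier3 at -2.16, Dusp4 at -1.16 and Phlda1 at -1.01), mesenchymal markers (-0.61, with Acta2 at -1.36 and S100a6 at -1.15), core spliceosome (0.13) and DNA replication (0.22, with E2f1 at 0.56). Other genes that fell were Galntl2 (-2.59), Fblim1 (-2.53), Etnk2 (-2.39), the annexin Anxa2 (-2.34), Ndrg2 (-2.32), Acvrl1 (-2.31), Actg2 (-2.31) and Klc3 (-2.29). Genes that rose included Rln1 (3.4), G0s2 (2.68), the serotonin receptor subunit Htr3b (2.52), Runx1t1 (1.99), Msl3l2 (1.77), Fxyd6 (1.74) and Igfbp6 (1.46). In all 47 genes were higher and 344 lower past the rule, of 11580.

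The Mbnl knockdown moved fewer genes past the rule, 88 higher and 30 lower of 11604. The smooth muscle actin gene Acta2 fell from 3.82 CPM (3.35 to 4.33) to 0.426 (0.267 to 0.645), Myl9 from 4.21 to 0.949 and Actg2 from 3.93 to 1.01. The annexin Anxa6 fell from 272 (268 to 276) to 97.9, and Npas4, Asb2 and Npy fell by 2.17, 1.72 and 1.46 on the log2 scale. The actin-binding Avil rose from 2.78 (2.39 to 3.23) to 10.5 (9.62 to 11.4), and Fa2h, Apol9b, Plcl1, Pde4c, Irs3, Col28a1 and Spnb1 rose by 1.84 to 1.99 from less than 1 CPM. All 23 measured cholesterol biosynthesis genes were lower than control, with a median of -0.47 (random lists -0.13 to 0.04); Tm7sf2 stood at -0.99, Nsdhl at -0.89 and Acat2 at -0.71, none past the rule. Medians below the range of random lists were those of DNA replication (-0.2, 39 of 40 genes lower), glycolysis and hypoxia (-0.19) and cytosolic ribosomal proteins (-0.17, 55 of 56 lower). Above it were those of mitosis (0.04) and the unfolded protein and amino acid response (0.05). Since genes of a list may move together between any 2 libraries, these shifts cannot be assigned to the knockdown. Both knockdowns raised 6 and lowered 13 genes past the rule, with 6 in opposite directions, where independent lists would share 0.355 and 0.886. Across genes, which are not independent replicates, r was 0.127 and the covariance 0.015, where unchanged libraries simulated with counting error only against the same control gave 0.465 and 0.00383 and shared 0 genes.

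Within the range of random lists in the Mbnl knockdown were tissue-regulated splicing factors (median -0.05, with Mbnl1 and Mbnl2 the members past the rule), SR proteins (-0.01), hnRNP proteins (-0.08), core spliceosome (-0.06), neuronal genes (-0.02, with Dcx higher at 1.76), REST targets (0.03), axon guidance and adhesion (0.06), p53 targets (0.04, with Ccng1 at -1.04), interferon response (-0.04), immediate early genes (-0.07), mesenchymal markers (0.03) and oxidative phosphorylation (0.02). In the Nacc1 knockdown they were tissue-regulated splicing factors (0.01, with Celf5 at -0.99 and Rbfox2 at -0.53), SR proteins (0.13), hnRNP proteins (0.09), axon guidance and adhesion (-0.01, with Slit1 at -1.71, Unc5a at -1.44 and Sema3f at -1.41), mitosis (0.07), p53 targets (0.04, with Btg2 at -2.22 and Sesn2 at 1.03), interferon response (-0.27, with Psmb8 at -1.33), the unfolded protein response (0.09), ribosomal proteins (0.06) and oxidative phosphorylation (0.1). Glial, epithelial and immune markers had fewer than 5 measured genes here. Cnp stood at 0.09 and -0.56, Grhl2 at 0.03 and -0.12, and Cd68, with 33 to 65 counts, at 1.21 and 0.82.

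Between the experiments exon differences were nearly uncorrelated, while exons called lower in both, and exons called in opposite directions, outnumbered those of independent lists. Across 19385 exons, which are not independent replicates, r was -0.017 between the Mbnl and Srrm4 knockdowns, 0.01 between Mbnl and Zfp871, 0.043 between Nacc1 and Srrm4, and 0.04 between Nacc1 and Zfp871, each against its own control. Exons lower by the size rule in the first and by the likelihood ratio test in the second experiment numbered 5, 8, 11 and 10 (1.3, 0.951, 1.48 and 1.08 for independent lists), and 0 were higher in both. A 29-nt exon of Strada, picked after its values were seen, was at -49.3 points in the Mbnl, -46.1 in the Nacc1, -19 in the Srrm4 and -27.2 in the Zfp871 knockdown. A 30-nt exon of Arfgap1 was at -44.2, -41.9, -26.8 and -30, and a 24-nt exon of the clathrin adaptor gene Picalm at -37.5, -39.3, -20 and -13.8. Called in opposite directions were 16, 12, 5 and 3 exons (1.14, 0.715, 0.871 and 0.5 for independent lists).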

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

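The tests of shared controls, of the letters, of counting noise, of mixing with Mbnl knockdown RNA and of the Mbnl1 level were chosen only after the result was seen.

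Under Srrm4 and Zfp871 knockdown 7 genes were called in opposite directions, and they are listed because the difference between both knockdowns was tested and called (edgeR, n = 2 per group). The number that independent lists would give was not computed, so no excess over chance is claimed. Because they were picked as opposite against the same control, their difference partly restates that choice. Arpp21, which encodes a phosphoprotein regulated by cyclic AMP, rose under Srrm4 knockdown by 0.98 and changed by -1.03 under Zfp871 knockdown, a difference of -2.01 (SE 0.17, edgeR adjusted p = 0.00865); its libraries stood at 10.5 and 10.9 CPM in control, 20.1 and 22.3 after Srrm4 and 4.75 and 5.68 after Zfp871 knockdown. The acyltransferase gene Agpat3 was at 0.56 and -1.23 (difference -1.79, SE 0.11) and the growth factor receptor Egfr at 0.76 and -0.78 (-1.54, SE 0.14). The Wnt antagonist Dkk1 was at 0.41 and -0.77 (-1.18, SE 0.08) and the phosphatase gene Ptprj at 0.55 and -0.61 (-1.16, SE 0.11). Tex261 was at 0.52 and -0.56 (-1.08, SE 0.1), and Ostm1 at 0.49 and -0.54 (-1.03, SE 0.09).

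Microexons were lower under both Srrm4 and Zfp871 knockdown. Against chance values of the shared controls, microexon differences correlated at 0.659 and 0.654 with no library in common. Against high controls, the second control differed from the first by a median of -0.06 points (SD 6.24, n = 65 microexons lowered in both). The difference under Zfp871 knockdown was -23.59. Against mixing with Srrm4 knockdown RNA, the 582 genes called there showed a share of 0.25 of their change under Zfp871 knockdown. For 119 lowered microexons the share was 0.721. A shift common to a letter cancels by design, since every group holds both letters. Within the letters the microexon median minus that of longer exons was -2.7 and -4.03 points under Zfp871 knockdown, which adds no separate argument. A lower Srrm4 level under Zfp871 knockdown, at a log2 fold change of -0.73, may underlie the pattern and cannot be told apart from a separate action of Zfp871: of exons lowered by 10 points under Zfp871 knockdown in 1 letter, 58.8% and 63.2% were lower under Srrm4 knockdown in the other, and of microexons 98% and 89.6%. The lower of these values meets the bound set in advance against this explanation, under 60%, but that bound was wrong, because a fall of 10 points in 1 library takes in exons lowered by sampling noise (all exons: 43.4% and 45.5% lower), while of exons lowered by the likelihood ratio test, examined afterwards against the first control, 72 of 74 microexons (97.3%; 69% of all microexons) and 68 of 91 longer exons (74.7%; 50.4% of all longer exons) were lower. For this explanation the bound set in advance was over 80% of all lowered exons. In this later comparison 140 of 165 (84.8%) were lower, against 50.8% of all exons so compared. The longer exons alone fall short of 80%, but that split was made after seeing the data. Their list may also hold more false calls, since in simulated unchanged groups 0.35 of 25.8 calls were lowered microexons. The explanation stays open because no library restores Srrm4 and because Rbms3, another gene for an RNA-binding protein, fell in both knockdowns.

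In the first experiment 77 exons passed the size rule in the same direction after knockdown of Mbnl1 with Mbnl2 and after knockdown of Nacc1. Against an unusual control library, these exons lay only 1.7 points (median, SD 6.86, n = 77) closer to the knockdowns in the second control, where the Nacc1 difference was 29.5. Against counting noise, simulated unchanged libraries shared 0.2 exons on average. Against Mbnl knockdown RNA mixed into the Nacc1 library, Mbnl2 had a log2 fold change of 0.00 there, and Nacc1 itself stood at 52 CPM against 223 in the Mbnl knockdown. A lower Mbnl1 level in the Nacc1 library (log2 fold change -0.59) may explain part of the overlap. With 1 library each, it cannot be told whether this difference exceeds the spread between libraries. The control libraries a and b of the second experiment stood at 103 and 121 CPM for Mbnl1. They stood at 59.5 and 41.3 for Mbnl2 and at 67.8 and 95.6 for Srrm4. Of the 77 exons 50 were shifted less in the Nacc1 than in the Mbnl knockdown (ratio of the medians 0.878). These exons had to differ by at least 20 points in both knockdowns, which draws the ratio toward 1. Exons past the rule in the Mbnl knockdown alone are left out, so the ratio does not decide the question. With 1 library per group, the lower Mbnl1 level cannot be told apart from a separate action of Nacc1 on the same exons.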

How the results depend on the processing

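The likelihood ratio test, the tests with trended dispersions, limma with the block and the splits by letter were chosen only after the result was seen; the other settings were planned. Of 568 named genes, exons and values 0 reversed. For single genes and exons, planned settings outside leaving out a library kept the call or its absence 2641 times, gained a call 194 times, lost the call or the size rule 143 times and moved in size 41 times. Leaving out a library kept 769, lost the call or the size rule in 353 and moved 28. Outside leaving out a library, 91 planned counts and summaries kept their side or stayed within 1.5 times, and 29 moved further. The cause of the changes below was not tested except where fewer libraries, fewer exons or a changed threshold enter by construction.

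The genes changed by Srrm4 knockdown, the genes changed by Zfp871 knockdown and the genes changed between Srrm4 and Zfp871 knockdown (582, 358 and 1374) numbered 573 and 364 with RLE factors for the knockdowns, 1743, 1355 and 2426 with DESeq2, 138 and 111 with a 2-fold threshold, and 0 and 178 with only the 4 libraries of the comparison. Of the targeted genes in every library, Srrm4 stayed at -1.59 with those 4 libraries (edgeR adjusted p = 0.081; range over its alternatives 3.39e-12 to 0.152). Of the list calls (8 and 9 of 19 by camera), 0 and 0 held with an estimated correlation. Tested against no change instead of against other genes, fry called 4 and 1, of which 3 and 1 are camera calls.

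With a replicate block by column letter the genes changed by Srrm4 knockdown, the genes changed by Zfp871 knockdown and the genes changed between Srrm4 and Zfp871 knockdown numbered 4565, 3854 and 5191. Leaving out 1 library at a time with the block gave 2203 to 3692 (2878 without control a, 2503 without control b, 2203 without Srrm4 knockdown b), 1878 to 3803 (2308 without control a, 1878 without control b), and 3000 to 5143 (3000 without Srrm4 knockdown b). Equal letters deviated together from the group means in genes (r = 0.749, 0.662 and 0.637 between pairs of groups; first principal component, 36.7% of the variance, parting the letters) more than in exons (0.042, 0.038 and 0.025). With the replicate block the quasi-likelihood test called 37 exons under Srrm4 and 1, a microexon, under Zfp871 knockdown, and limma 0 under Srrm4 knockdown. The likelihood ratio test with the replicate block called 390, 308 and 304 exons, with 85 lowered microexons under Zfp871 knockdown. The letters are not the replicate numbers of the labels, and no source says what they pair.

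Of exons, 25 were called under Srrm4 knockdown: 16 with at least 20 reads per library, 11 by limma, 12 and 14 with trended dispersions in legacy and robust form, 1 with only the 4 libraries, 42 among exons of the authors' filtered table, and 282 by the likelihood ratio test (25.8 on average in simulated unchanged groups). That test called 185 exons under Zfp871 knockdown, 75 of them lowered microexons, and 169 between the knockdowns. It called 24 exons in host genes of Mbnl targets under Srrm4 knockdown, and 34 (neural microexon hosts) and 16 (Mbnl target hosts) under Zfp871 knockdown. The correlation of both exon responses, 0.56 with all libraries, was 0.21 and 0.167 with split controls and 0.208 and 0.187 with split letters.

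In the first experiment the cassette exons past the size rule in Mbnl1 and Mbnl2 knockdown numbered 436 at 10 points and 83 at 30 points, and the cassette exons past the size rule in Nacc1 knockdown 462 and 67, and 278 at 20 points without the rule on intervals. Genes numbered 223 for Mbnl at 20 counts, and 44 and 259 at 200 counts.

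Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 0 to 180 genes under Srrm4 knockdown (20 without control a, 0 without control b, 180 without knockdown a, 0 without knockdown b), 0 to 29 under Zfp871 knockdown (29 without control a, 0 without each other) and 0 to 530 between them (530 without Srrm4 knockdown a, 0 without each other). Exons by the quasi-likelihood test numbered 0 to 0 in all 3 comparisons, lowered microexons 0 to 0 in both, and other events 0 to 21 and 0 to 26 (21 and 26 without control a). Srrm4 ranged from -1.83 to -1.3 and Zfp871 from -2.1 to -1.52 in their own knockdowns. Depth sets which exons can be counted: 36176 exons had 20 reads in all libraries of the first experiment.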

Other observations

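The list tests were planned, and setting all 4 knockdowns side by side was chosen only after the result was seen. Genes of cholesterol biosynthesis were mostly lower than control in all 4 knockdowns, with no member called or past the size rule. The median log2 fold change over the 23 genes was -0.47 in the Mbnl knockdown (0 genes higher, 23 lower), -0.21 in the Nacc1 knockdown (2 and 21), -0.18 in the Srrm4 knockdown (4 and 19) and -0.16 in the Zfp871 knockdown (3 and 20). Tm7sf2, a sterol reductase gene, stood at -0.99, -0.51, -0.98 and -0.87, Nsdhl at -0.89, -0.10, -0.18 and -0.16, and Acat2 at -0.71, -0.21, -0.26 and -0.27. The median lay below random lists of independently drawn genes in both knockdowns of the first experiment. Camera called the list in both knockdowns of the second (camera adjusted p = 0.00206 and 0.00534). With an estimated correlation it did not (camera adjusted p = 0.617 and 0.619). The 4 comparisons rest on 2 controls, so knockdowns that share a control do not give independent values. No explanation was tested.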
